A study of Homo sapiens with 6 samples.

How the data were processed

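Gene expression was measured by RNA sequencing in 6 libraries, 3 labelled olaparib and 3 labelled DMSO, all labelled as the colorectal carcinoma line RKO. Per the labels' protocols, cells were plated the day before treatment, total RNA was extracted with a column kit that keeps small RNAs, and libraries followed standard Illumina procedures. The olaparib dose, the length of treatment, the selection of RNA and whether the libraries keep strand are not given in the sources used here. The submitters' processing notes name fastp, STAR and the genome build hg38, and the authors deposited 1 table of raw read counts, with 39396 gene symbols and a column for each library. The counting program, its strand setting and the gene annotation are not given in the sources used here. No row lacked a gene name and no symbol occurred more than once. In every library more genes held 2 counts than 1, as when both reads of a pair are counted, so intervals and floors from counts are too narrow, and they cover counting error only.

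Groups and replicate numbers were taken from the sample titles, which match the column names of the table. Library totals ran from 28715138 to 42423785 counts. Pairs of libraries within a group differed by more than sampling noise, so each was counted as a separate replicate. Over genes with at least 20 counts, the chi-square per degree of freedom was 4.74 for olaparib replicates 2 and 3. The other pairs within groups gave 24.0 to 68.6. Counting both reads of a pair would raise these values, and they do not tell separate cultures from technical copies. Gene types and positions came from GENCODE release 29 on the same genome assembly, matched by symbol for 99.6% of rows. Reads from overlapping genes, antisense partners and near-identical copies cannot be separated in such a table, which concerns the metallothionein, histone, ribosomal protein, HLA and protocadherin genes most.

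Counts were tested with edgeR 4.0.16 in R 4.3.3, with its default expression filter, TMM scaling, robust quasi-likelihood dispersions and treatment group as the only term. P-values were adjusted by the Benjamini-Hochberg method and genes were called at 0.05. Levels are CPM, counts relative to the TMM-scaled library size, as mean ± SD over 3 libraries. Standard errors of log2 fold changes were derived from the F statistic. A fold against a group without a count was computed against a floor of 3 counts over the group's 3 libraries and is given as a lower bound. Where a group held 1 to 3 counts, the ratio is given with its 95% counting interval.

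There were 29 gene lists with 860 entries, covering DNA repair, the cell cycle, p53, interferon, acetyltransferases, metabolism, ribosomes and markers of intestinal, fibroblast, blood and endothelial cells. Lists with at least 5 tested members were compared with other genes by camera in limma 3.58.1, with a preset correlation between genes of 0.01. Alternatives were camera with an estimated correlation and fry. Camera asks whether a list moved relative to other genes, whereas fry asks whether its own genes moved, on balance, 1 way, or, in its mixed form, in either direction. The named genes were 11 genes fixed by name, the 10 largest rises and 10 largest falls among called protein-coding genes with a mean of at least 1 CPM and no overlap between groups, up to 4 members of each list with the smallest adjusted p, and the genes with the largest share of counts. The lists, this rule, the design and the alternatives were chosen before the data were examined, except where the text says otherwise.

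On data simulated for olaparib against DMSO over 16139 genes, the test recovered 24% of the genes changed 1.5-fold, 74% of those changed 2-fold, 96% at 4-fold and 98% at 8-fold. Of 158 calls there, 12 were false (7.59%). Only 50 genes were changed at each fold, whereas 75.7% of genes were called in the real data. The adjusted threshold was therefore stricter in the simulation, and its recovery does not carry over to the real comparison. Camera called the 1 list that was shifted and 0 of 28 that were not. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often camera calls lists whose genes vary together, such as ribosomal proteins (estimated correlation 0.83).

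Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, library size alone, 2 other expression filters, the replicate number as a block, the loss of each library in turn and other fold thresholds. Division of all counts by 2, a test against a 2-fold change and the count of genes present in 1 group alone were added after seeing the data. Genes that tell the sex of cells were not eligible for naming and are not drawn. Some genes that the naming rule selects are not reported here.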

Results

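Olaparib inhibits the PARP enzymes, which sense DNA strand breaks, and the title of the study links its effect in colorectal cancer to the acetyltransferase KAT2B and to RAD51C, a protein of homologous recombination. The single comparison that the labels give is olaparib against the solvent DMSO, with 3 libraries each. Directions are between libraries as labelled, and a difference in cell source could not be told apart from treatment. No difference below is therefore assigned to olaparib. The DMSO libraries held 41204441, 29544974 and 42423785 counts and the olaparib libraries 29579729, 31387990 and 28715138. Nothing says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

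RAD51C was 2.04-fold lower in the olaparib libraries, at 28.3 ± 0.391 CPM against 57.9 ± 1.73 CPM in DMSO (SD, n = 3). KAT2B did not differ by more than the spread between replicates, with 24.4 ± 1.46 CPM in olaparib and 23.7 ± 3.15 CPM in DMSO. PARP1, the main target of olaparib, was 2.24-fold lower, at 443 ± 32.7 against 990 ± 173 CPM. BRCA2, a gene of homologous recombination, was 1.47-fold higher, at 52.7 ± 3.52 against 35.8 ± 9.64 CPM. The p53 targets CDKN1A and MDM2 showed no called difference, with log2 fold changes of -0.08 ± 0.18 and 0.17 ± 0.11 (SE), nor did the repair genes PARP2 (-0.17 ± 0.10) and BRCA1 (0.03 ± 0.12).

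RAD51C lies on chromosome 17 from 58692573 to 58735611 and KAT2B on chromosome 3 from 20040023 to 20154404 (hg38). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change of RAD51C was -1.03 ± 0.10 (SE, adjusted p = 1.1e-06), with all 3 olaparib libraries below all 3 DMSO libraries. Of 5455 genes of similar expression, 32.1% differed by as much as RAD51C, and the 61 other protein-coding genes tested within 5 Mb of it had a median of -0.46. The same test gave KAT2B 0.04 ± 0.13 (adjusted p = 0.792), PARP1 -1.16 ± 0.14 (adjusted p = 9.58e-06) and BRCA2 0.56 ± 0.16 (adjusted p = 0.00759). Regions of KAT2B and PARP1 were also lower, over protein-coding genes with at least 5 CPM in both groups. The median was -0.81 for 42 genes at 20 to 40 Mb of chromosome 3, which holds KAT2B. It was -0.65 for 81 genes at 220 to 240 Mb of chromosome 1, which holds PARP1. Whether either gene moved apart from its region was not tested. KAT2A, the paralog of KAT2B, was 1.19-fold lower by edgeR's test (-0.25 ± 0.09, adjusted p = 0.0252). The sign of KAT2B turned with library size alone (-0.03), without DMSO replicate 2 (-0.07) and without olaparib replicate 1 (-0.01). Under edgeR, the KAT2A call was lost without olaparib replicate 1, 2 or 3 (adjusted p = 0.0757, 0.1 and 0.0805), and PARP2 passed with library size alone (-0.23, adjusted p = 0.0484).

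**Figure D1:**
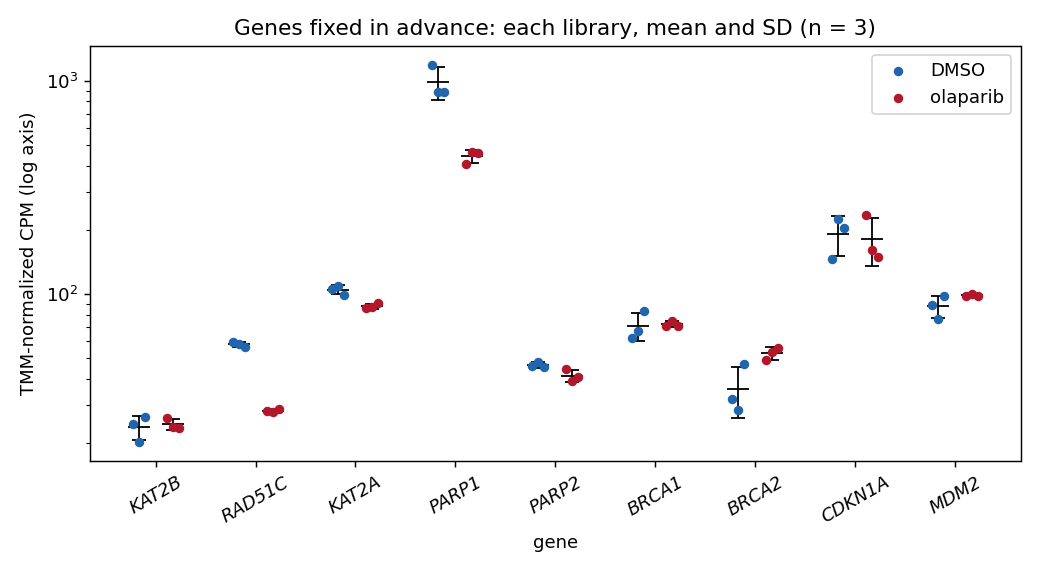
TMM-scaled CPM on a log axis for 9 genes fixed by name, with each library as a point and the mean and SD of 3 libraries in black, DMSO in blue and olaparib in red. RAD51C and PARP1 are lower in all 3 olaparib libraries, while the groups overlap for KAT2B, BRCA1 and CDKN1A.

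The largest rises were in genes without a count in any DMSO library. SPINK6, a protease inhibitor of skin, was at least 2262-fold higher, at 58.5 ± 1.70 CPM in olaparib. MLPH, which takes part in melanosome transport, was at least 1198-fold higher, IGFBP1, a binding protein of insulin-like growth factors, at least 866-fold, and the transcription factor FOXN1 at least 716-fold. SLITRK4 was at least 760-fold higher, MT1E, a metallothionein with close paralogs, at least 638-fold, and MGMT, which removes alkyl groups from guanine, at least 615-fold. TDRD9 held 1 DMSO count, for a ratio of 6033 (95% counting interval 1082 to 238350), and ERVV-2, a gene of retroviral origin, held 2, for a ratio of 4339 (1201 to 35834), and DMSO replicate 2 held all of these DMSO counts.

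The largest falls were in genes without a count in any olaparib library. KIF1A, a motor of synaptic vesicle transport, stood at 196 ± 36.8 CPM in DMSO and was at least 5850-fold lower in olaparib. PCSK1N, DPYSL5 and POU4F1 were at least 3054-fold, 2264-fold and 2305-fold lower. AMOT, a regulator of the Hippo pathway, was at least 3531-fold lower, IGFBP2 at least 2688-fold, BEX4 and BEX2 at least 2584-fold and 2425-fold, GPR27 at least 2206-fold and PCDH10 at least 2205-fold.

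Of 17078 genes tested by edgeR's quasi-likelihood test, 12927 were called (75.7%), 6045 higher and 6882 lower in olaparib. Among them 8028 differed by at least 2-fold, 3763 higher and 4265 lower, and 555 were higher and 1268 lower by at least 16-fold. The median absolute log2 fold change was 0.94 over all tested genes. The median SD within groups was 0.136 (log2 CPM), over genes with a mean log2 CPM of at least 1 only. In 79.4% of genes the groups did not overlap, where chance gives 10%. By a definition set after the data were seen, 194 genes reached a mean of 10 CPM in DMSO and stayed below 0.1 CPM in olaparib, and 27 did the reverse. Log CPM correlated across genes, which are not independent replicates, at r = 0.984 to 0.992 within groups and 0.751 to 0.762 between them, and the first principal component, which separated the groups, held 94.1% of the variance. The labels give the same cell line for both groups. Even so, 7 of 7 markers of HEK293 cells, chosen after the result was seen, were at 1 CPM or more in DMSO and below it in olaparib. The groups may therefore hold different cells, which was not tested against a profile of either line. Every gene group was compared between these same libraries, so each count of members stands beside the 75.7% of all genes that were called.

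**Figure D2:**
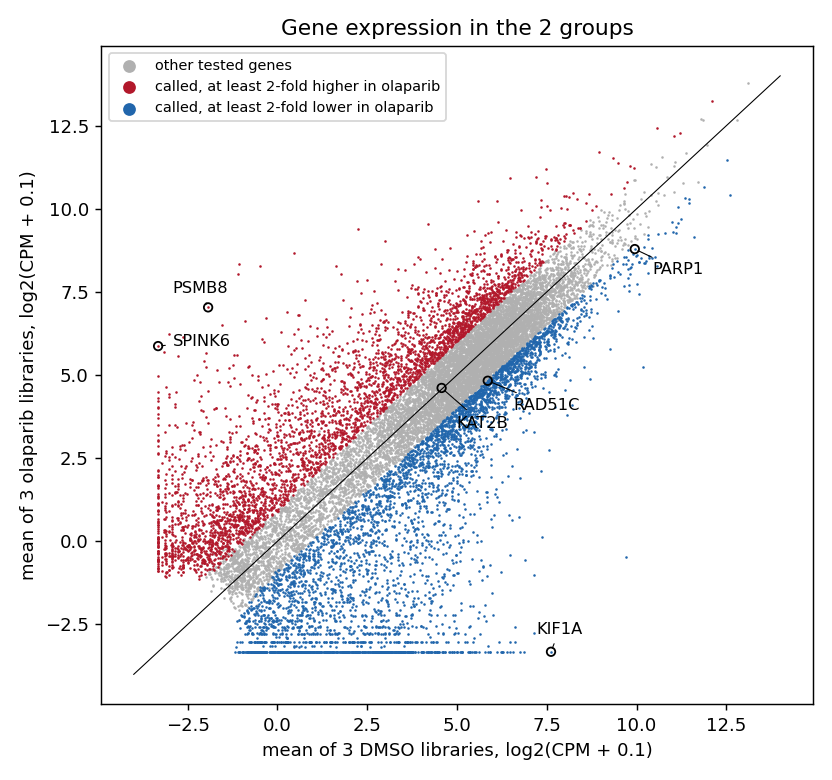
Mean of 3 olaparib libraries against the mean of 3 DMSO libraries, both as log2 of CPM plus 0.1, with each of 17074 points a tested gene and the diagonal marking equal levels. Genes called with at least a 2-fold difference are red where higher in olaparib and blue where lower, and the points along the left and lower edges are genes without a count in 1 group.

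Most ribosomal protein genes were lower in the olaparib libraries. Of 78 genes for cytosolic ribosomal proteins, 68 were lower in olaparib, 1 was higher and 9 did not pass, with a median log2 fold change of -1.22. RPL36 was 5.84-fold lower (122 ± 1.61 against 714 ± 146 CPM), RPSA 5.48-fold, RPL9 4.80-fold and RPL30 3.42-fold. Nuclear genes of oxidative phosphorylation followed, with 35 of 45 lower, 4 higher, 6 not passing and a median of -0.78. ATP5MC3 was 3.49-fold lower, COX6B1 2.87-fold and SDHB 2.40-fold, while SDHA was 2.81-fold higher. SDHA lies in the first 20 Mb of chromosome 5. All 36 protein-coding genes there with at least 5 CPM in both groups were higher (median log2 fold change 1.46). In contrast to the nuclear genes, 11 of 13 mitochondrially encoded genes were higher, 1 was lower and 1 did not pass, with a median of 0.85. MT-CYB was 2.24-fold higher, MT-ND4 2.21-fold, MT-ATP6 2.08-fold and MT-ATP8 1.87-fold. Mitochondrial transcripts took 6.75, 5.99 and 5.22% of counts in the olaparib libraries and 3.72, 3.83 and 3.86% in DMSO, and MT-CO1 was the gene with the most counts in every library.

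Genes of DNA replication and S phase were also mostly lower, with 32 of 48 lower, 4 higher, 12 not passing and a median of -0.84. GINS1, a part of the replicative helicase, was 7.58-fold lower, PCNA, the sliding clamp of DNA polymerase, 4.98-fold and SLBP, which binds histone mRNA, 4.11-fold. PCNA lies in the first 20 Mb of chromosome 20, where 63 protein-coding genes with at least 5 CPM in both groups had a median of -1.43. Histone genes whose expression is tied to replication went the other way, with 16 of 32 higher, 2 lower and 14 not passing; H3C8 was 49.4-fold higher, H2BC9 12.1-fold, H4C8 7.49-fold and H2AC6 3.06-fold. These mRNAs mostly lack a poly(A) tail, so their level depends on how RNA was selected.

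Genes of the cholesterol biosynthesis list were higher almost throughout, 23 of 25, with 1 lower, 1 not passing and a median of 1.34. The synthesis enzymes HSD17B7 and DHCR7 were 3.72-fold (log2 1.90 ± 0.11, SE) and 3.71-fold (1.89 ± 0.11) higher. Of 26 genes of NF-kB and inflammatory cytokines, 17 were higher, 2 lower and 7 did not pass, with a median of 1.25. The adhesion molecule ICAM1 was 25.6-fold higher, TNFAIP2 15.5-fold, BIRC3 11.1-fold and the cytokine LIF 9.75-fold. Of 20 genes of the xenobiotic response and ABC transporters, 17 were higher, 2 lower and 1 did not pass, with a median of 1.51. ABCC2, ABCC3 and CYP1B1 were 8.53-fold, 6.92-fold and 5.66-fold higher. ABCB1, the efflux pump known to export olaparib, held 2 counts in the olaparib libraries against 19.99 ± 3.31 CPM in DMSO, a ratio of 889 (95% counting interval 246 to 7346), and both counts were in olaparib replicate 3.

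Camera called 8 of the 28 lists tested, 3 lower and 5 higher in olaparib. Its adjusted p was 2.5e-07 for ribosomal proteins, 9.58e-06 for cholesterol, 0.000513 for oxidative phosphorylation and for the xenobiotic list, 0.000747 for NF-kB, 0.000889 for DNA replication, 0.0102 for mitochondrially encoded genes and 0.0208 for histones. With an estimated correlation none of these calls held: adjusted p = 0.347 with an estimated correlation for the xenobiotic list, adjusted p = 0.484 with an estimated correlation for histones, and adjusted p = 0.69 with an estimated correlation for the other 6. Fry called 19 lists by direction and all 28 in its mixed form. Adjusted over the list alone, the counts of members higher and lower were the same in each of the 29 lists, except that 12 mitochondrially encoded genes were higher.

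**Figure D3:**
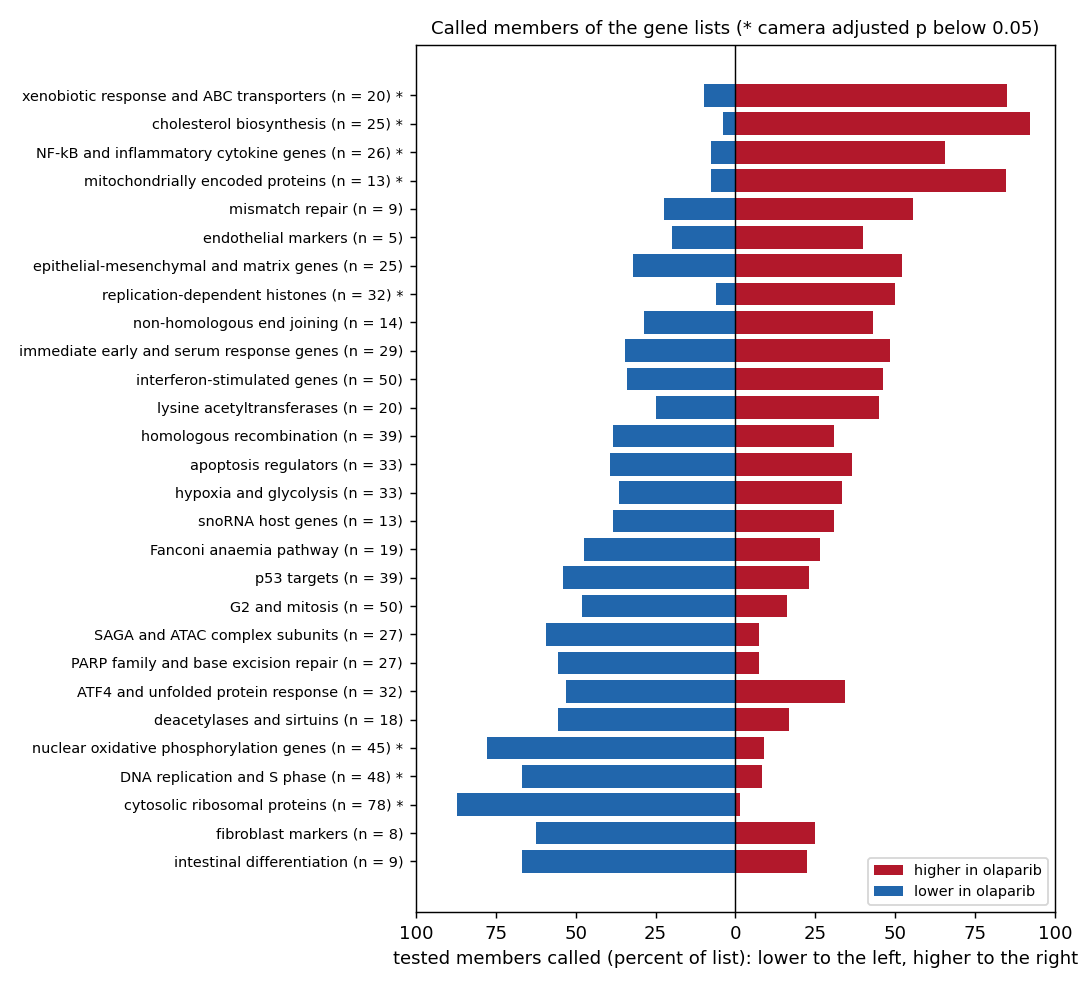
Percent of tested members of each gene list called higher (red, to the right) or lower (blue, to the left) in olaparib, ordered by the median log2 fold change of the list, with the number tested in brackets and an asterisk where camera called the list. The bars of ribosomal proteins reach furthest to the left, with 68 of 78 lower, and those of cholesterol synthesis furthest to the right, with 23 of 25 higher.

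DNA repair genes moved both ways and camera called none of their lists. In homologous recombination 12 of 39 genes were higher, 15 lower and 12 did not pass: ATM, the kinase that signals strand breaks, was 5.76-fold higher (320 ± 1.46 against 55.5 ± 12.2 CPM) and PALB2 2.94-fold higher, while RPA2 was 3.60-fold and XRCC3 2.82-fold lower. Of 19 Fanconi anaemia genes 5 were higher and 9 lower, with FAN1 2.11-fold higher and CENPX, UBE2T and FAAP100 2.59-fold, 2.57-fold and 2.19-fold lower. Among 27 PARP family and base excision repair genes 2 were higher and 15 lower, with MBD4 3.32-fold higher and NEIL3, POLB and FEN1 2.32-fold, 2.16-fold and 2.06-fold lower. In end joining 6 of 14 were higher and 4 lower, with LIG4 3.97-fold, TP53BP1 2.97-fold and POLM 2.66-fold higher and MAD2L2 2.31-fold lower. In mismatch repair 5 of 9 were higher and 2 lower, and MLH3 and MSH6 were 2.91-fold and 2.08-fold higher.

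Of 39 p53 targets, 9 were higher, 21 lower and 9 did not pass. EDA2R was 193-fold lower, with 4 counts over the olaparib libraries (count ratio 211, 95% counting interval 82.1 to 775). SESN2 was 6.51-fold and BTG2 5.04-fold lower, and PLK3 was 5.41-fold higher. Among 33 apoptosis regulators 12 were higher and 13 lower, with the death receptor TNFRSF10A 8.55-fold higher and PMAIP1 and HRK 14.2-fold and 9.62-fold lower. In G2 and mitosis 8 of 50 were higher and 24 lower, and BIRC5, SPC25, MAD2L1 and TACC3 were 5.22-fold, 3.09-fold, 2.85-fold and 2.13-fold lower. Camera called none of these 3 lists.

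Among subunits of SAGA and ATAC, the complexes in which KAT2A and KAT2B act, 2 of 27 were higher and 16 lower. TAF12 was 3.66-fold lower, TADA1 2.83-fold, TAF5L 2.12-fold and TADA2B 2.03-fold. Camera did not call this list (adjusted p = 0.0825), but did without DMSO replicate 2 (adjusted p = 0.0404); over all libraries it gave adjusted p = 0.65 with an estimated correlation. Of 20 lysine acetyltransferases 9 were higher and 5 lower, with NCOA3, KAT6B and TAF1 2.28-fold, 2.07-fold and 1.71-fold higher and NCOA1 2.60-fold lower. Of 18 deacetylases and sirtuins 3 were higher and 10 lower, with HDAC9 and HDAC7 7.68-fold and 6.64-fold higher and HDAC11 and SIRT2 3.74-fold and 2.84-fold lower. Camera called neither of these.

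Interferon-stimulated genes split, with 23 of 50 higher, 17 lower and 10 not passing. PARP14 was 94.4-fold higher, SAMD9L 23.7-fold, APOL6 22.3-fold and DDX60L 12.2-fold. Of 29 immediate early genes 14 were higher and 10 lower: JUN fell from 1155 ± 464 to 37.6 ± 2.58 CPM and ARC was 37.6-fold lower, while the phosphatases DUSP5 and DUSP4 were 9.08-fold and 7.37-fold higher. In hypoxia and glycolysis 11 of 33 were higher and 12 lower, with VEGFA and ADM 2.85-fold and 2.81-fold higher and CA9 and EGLN3 16.2-fold and 5.28-fold lower. In the ATF4 and unfolded protein response 11 of 32 were higher and 17 lower, with DDIT4 3.86-fold higher and PHGDH and MANF 3.67-fold and 3.44-fold lower. Of 13 host genes of small nucleolar RNAs 4 were higher and 5 lower, with TAF1D and ZFAS1 2.39-fold and 1.91-fold higher and SNHG16 and SNHG15 2.21-fold and 1.77-fold lower. Camera called none of these 5 lists.

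Markers of cell type also differed between the groups. Of 9 tested genes of intestinal differentiation 6 were lower, 2 higher and 1 did not pass. CDX2, the intestinal transcription factor, had no count in olaparib and 24.5 ± 2.0 CPM in DMSO (at least 713-fold lower), and CA2 held 2 olaparib counts, both in replicate 2 (ratio 4446, 95% counting interval 1231 to 36715). HNF4A was higher, with 12 DMSO counts (ratio 93.7, 95% counting interval 53.3 to 182), and its log2 fold change moved from 6.47 to 7.59 without DMSO replicate 2. In the epithelial-mesenchymal and matrix list 13 of 25 were higher and 8 lower, with CLDN4, MMP14 and THBS1 41.8-fold, 39.0-fold and 14.9-fold higher and TNC without a count in olaparib (at least 1724-fold lower). Of 8 fibroblast markers 2 were higher and 5 lower, with COL5A1 3.63-fold higher and LUM, COL3A1 and FAP 89.9-fold, 12.9-fold and 3.36-fold lower; LUM moved from -6.49 to -7.08 (log2) without olaparib replicate 1. Of 5 endothelial markers 2 were higher and 1 lower, with CDH5 at 20.5 ± 0.106 CPM in olaparib and 0.128 ± 0.182 in DMSO, where replicate 2 held 0.337 and replicate 3 none. Of 4 blood markers, too few for camera, ITGAM and HBA1 were lower and none was higher. HBA1 held 8 counts in olaparib and 42 in DMSO, and edgeR did not call it without olaparib replicate 1 (adjusted p = 0.0839), without olaparib replicate 3 (adjusted p = 0.0946) or with no filter beyond 1 count (adjusted p = 0.0538), nor did DESeq2 (adjusted p = 0.0898). Without olaparib replicate 2 HBA1 moved from -1.95 to -3.23 (log2), and without olaparib replicate 3 ITGAM moved from -2.94 to -3.81. Camera called none of the other 4 lists, and the median, mean and direction of the test did not all have the same sign for the epithelial-mesenchymal, interferon, hypoxia and apoptosis lists.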

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

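The count of genes higher, lower or changed at least 2-fold stayed within 1.5 times under every alternative run, and 90.1 to 99.6% of the calls were shared, 0 of them with opposite sign; division of counts by 2, a test against a 2-fold change (6286 genes) and the count of genes present in 1 group alone were added after seeing the data. RAD51C stayed between -1.07 and -1.02 without each library, and 133 of the 138 other named genes kept their direction and call throughout, as did 6 of 28 lists. Camera called 0 lists with an estimated correlation (2 at an unadjusted p under 0.05) and fry, which asks a different question, called 19; with an estimated correlation camera also uses the residual degrees of freedom, so 2 choices changed at once. Results that were not called turned sign, and the cause was not tested: with library size alone KAT2B gave -0.031 and BRCA1 -0.044; the homologous recombination list gave 0.0076 with RLE size factors, 0.017 with the stricter filter and 0.0013 with the replicate block. Without each library in turn, KAT2B ranged from -0.075 to 0.11, CDKN1A from -0.31 to 0.058, BRCA1 from -0.073 to 0.14, the homologous recombination list from -0.084 to 0.0275, the apoptosis list from -0.083 to 0.017 and the snoRNA host list from -0.28 to 0.086. The median log2 fold change of all genes was -0.09 with TMM, -0.08 with RLE and -0.16 with library size alone. Same-numbered libraries did not deviate together (r = -0.25, -0.20 and -0.01), and no library correlated best with its own number. With 3 libraries in each group, this cannot show whether replicates were handled in pairs. The replicate block gave 12426 calls, KAT2A not among them (-0.25, adjusted p = 0.0642 by edgeR's test). The simulated recovery of 24% at 1.5-fold came from 158 calls among 16139 genes, whereas 75.7% of genes were called here. The adjusted threshold was therefore stricter in the simulation, and its recovery does not measure what a missing call means here. A missing call for a small difference still does not show that levels were equal.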

Other observations

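Several gene families not described so far differed between the groups, and they were chosen after their values were seen. All 6 HLA class I genes tested were higher in olaparib, as were all 5 genes of the immunoproteasome and the TAP peptide transporter. PSMB8, a proteasome subunit used in antigen processing, stood at 131 ± 9.21 CPM in olaparib (SD, n = 3) and at 0.285, 0.135 and 0.0678 CPM in the 3 DMSO libraries. HLA class II genes went the other way, with 8 of 11 lower and 1 higher, or 9 lower with library size alone. HLA-DQB1 had no count in any olaparib library and 25.3 ± 3.04 CPM in DMSO. Reads of HLA and protocadherin genes are shared with close relatives, so values of single members are uncertain.

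Of 10 S100A genes 9 were higher and none was lower, and S100A16 reached 297 ± 12.4 CPM against 20.96 ± 1.85. Of 15 keratins 10 were higher and 4 lower, among them KRT18 at 400 ± 64.5 against 75.3 ± 10.6 CPM. In the protocadherin beta cluster on chromosome 5, 10 of 11 genes were higher. HOX genes, which mark the position of origin of a cell along the body, split into 12 higher and 18 lower of 36, with HOXD13 at 0.114 ± 0.0374 CPM in olaparib and 64.0 ± 7.40 CPM in DMSO (edgeR's quasi-likelihood test). Other than the class II count, these counts were the same with RLE size factors and with library size alone.

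The tests of the HEK293 markers, of the other splits of the libraries and of the share of genes that changed as much as RAD51C were chosen only after the result was seen.

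The groups are labelled as 1 cell line but differ in 12927 of 17078 genes, and depth does not account for this, since 98.3% of the calls remained after every library was thinned to 28715138 counts. Medians of 148 segments of 20 Mb had an SD of 0.441 (log2), above the 0.433 that 95% of 10000 circular shifts of genes along the genome stayed under (permutation p = 0.0101), a narrow margin because shifts keep long blocks, and shuffled genes gave 0.186. The prediction set beforehand took an SD above this bound as going with different genomes, from another cell line or a selected subclone. It took such an SD as going against a response of cells that share 1 genome as the whole cause. The SD passed the bound, but the test cannot decide between these causes. Shifted genes keep their blocks and mainly change where blocks meet segment borders, so no conclusion is drawn from it. Neighbouring genes did differ together, since 95% of shuffles stayed under 0.186 and replicates of a group gave at most 0.0965. As an example picked as the highest segments after the values were seen, all 36 genes used between 0 and 20 Mb of chromosome 5 were higher in olaparib (median 1.46). So were all 23 between 20 and 40 Mb (1.19). A candidate explanation is HEK293-derived cells in the libraries labelled DMSO. There 7 of 7 markers were at 1 CPM or more, and in olaparib all were below it, by library size alone without TMM scaling. On that scale IRS4 (146 ± 74.4 CPM), NEFM (59.0 ± 1.89) and NEFL (56.6 ± 14.1) were highest in DMSO. No profile of HEK293 or RKO was used here, so how many of the 7 markers RKO expresses stays open. Cell source and treatment cannot be told apart where each group holds 1 of each, and 10 splits are too few to weigh chance. Of the 10, the real one gave 12927 calls by edgeR and the highest other 0 (at most 56 at an unadjusted p under 0.05, and 0 by limma-voom). Few calls were bound to result in the other splits, since each mixed both labelled groups and turned their difference into spread. The contrast therefore says nothing about chance.

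Lower ribosomal protein and oxidative phosphorylation genes form the second pattern. Short transcripts or GC content could shift such genes together, but the median of the 123 genes (-1.04) lay at percentile 0 of 10000 random lists matched on transcript length and expression, and at percentile 0 of those matched on GC content and expression. The matched lists had medians of 0.09 (95% range -0.17 to 0.30) and 0.08 (-0.17 to 0.30), which argues against either bias as the whole cause. Treatment, a difference in cell source and reads shared with pseudogenes stay open and were not tested for these genes.

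Lower RAD51C is the third pattern, and it may be part of the wide difference between the groups. Of 5455 genes within 1 log2 unit of its expression, 32.1% differed by as much in either direction and 17.01% were as low or lower. The 61 other protein-coding genes within 5 Mb had a median of -0.46 (95% bootstrap interval -0.68 to -0.04), an interval that includes -0.51, the midpoint between no change and RAD51C's value, so a shift of its chromosome region cannot be told apart from a change of the gene, given the spread of its neighbours. Regulation by KAT2B or olaparib stays open and untested, because cell source and treatment coincide here.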
